A study of Mus musculus with 2 samples.

How the data were processed

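Poly(A)-selected RNA from mouse embryonic fibroblasts was sequenced as paired-end libraries, per the labels' protocols, with 1 library from wild-type cells and 1 from SRSF10-deficient cells. The submitters' processing notes name TopHat as a tool and mm9 as the genome build, without a version for the tool. The program that estimated exon inclusion, its settings, its transcript annotation and the rule by which events entered the table are not given in the sources used here.

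The deposited table lists 100 alternative splicing events. Per the file headers it gives a posterior mean of the inclusion fraction with a lower and an upper bound for each library, the difference between both, and a Bayes factor. The deposited inclusion values are a fraction from 0 to 1, which was multiplied to a percentage here. The Bayes factor is a ratio computed by the authors, with a ceiling reached by 11 events. The level of the deposited intervals is not given in the sources used here. The table also holds, for each library, counts of reads by isoform class as deposited by the authors. These classes are reads that fit only the inclusion isoform, only the exclusion isoform, both, or neither. In the table, sample 1 was taken as the wild-type library and sample 2 as the deficient one, since the labels' descriptions give those names. All differences are written here as deficient minus wild-type, which turns the sign of the deposited difference.

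Inclusion refers to the first isoform of each event in the table. That is the isoform with the cassette exon, with the longer exon at an alternative splice site, with the retained intron, or with the upstream exon of a mutually exclusive pair. The table held 9 cells of assigned reads that a spreadsheet had turned into times of day. All 9 gave back the sum of inclusion-only and both-isoform reads, and these cells entered no result. Gene symbols were taken from the GENCODE M21 name table through the Ensembl identifiers of the table, and all 96 genes matched. For 11 genes the symbol differed from the one in the table. The row given as Colec12 carries the identifiers of Thrap3 and a small RNA gene, so it is called Thrap3 here. The table gave 2 gene identifiers for 6 events, of which the one matching the symbol, or else the protein-coding one, was used.

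For each event the inclusion-only and exclusion-only reads of both libraries were compared by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 100 events. An event passed at an adjusted p under 0.05, with an inclusion difference of at least 10 points and the same direction in those reads. With 1 library per genotype there is no replicate check. The test compares the 2 libraries and not the genotypes, and intervals cover counting error only, since reads from amplified libraries are not independent molecules. The events had been selected by the authors, so the share that passed says nothing about events outside the table. No p-value is given across events or genes. Every listed event already differed by at least 20 points between these same libraries, so passing is no independent support for a difference. Where a share is 0, the limit that 3 counts would give is printed. Shares of reads carry exact Clopper-Pearson 95% intervals. The share of inclusion-only reads is not corrected for the length of the alternative part. Its differences are therefore not on the scale of the deposited inclusion. The test was tried on simulated data with the real read depths of the 100 events in 50 runs. It recovered 33.0% of simulated differences of 20 points, 60.6% of those of 30 points and 88.9% of those of 50 points, and called 0.6% to 1.68% of unchanged events. The simulated reads were independent, the events were not selected for a difference, and only the adjusted p was applied. These rates therefore do not give the error among the listed events that passed.

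Coordinates are those of the table (mm9). Cassette exons were placed in GENCODE M21 transcripts of the same gene by the lengths of the exon and of both neighbouring introns, so no coordinate was converted between builds. An inclusion transcript was found for 63 of the 69 cassette exons.

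The rule for named genes was set before the data were examined. It took events that passed with at least 20 exclusive reads in each library, and among these the 10 cassette exons with the largest rise, the 10 with the largest fall, and the 3 largest of each other type and direction. It added any event in Lpin1 or Srsf10, and the 2 largest differences in each direction for each of 10 gene lists. The lists, also fixed beforehand, were splicing factors and RNA-binding proteins, SRSF10 targets reported in other cell systems, adipocyte differentiation and lipid metabolism, chromatin and transcription regulators, cytoskeleton, cell cycle with DNA repair and apoptosis, signalling by kinases, phosphatases and small GTPases, membrane trafficking, extracellular matrix and adhesion, and markers of other cell types. Some events that this rule would name are not reported here. The table holds no background of unchanged events, so no enrichment was tested.

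Alternatives fixed beforehand were counting each gene once, a minimum of 20 exclusive reads in each library, and a minimum difference of 20 points or none. They also included an adjusted p under 0.01, and dividing inclusion reads by 2 for cassette exons and retained introns, whose inclusion has 2 junctions. Inclusion-only reads can also lie inside the exon or intron, and a fixed divisor does not correct for its length. The authors' p-values, also planned, could not be used because the table gives a Bayes factor instead. Alternatives chosen after seeing the data were the event type by the isoform text, the share of inclusion-only reads in place of the deposited inclusion, a Bayes factor of at least 10, and leaving out 4 doubtful or near-duplicate events. Analyses ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.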

Results

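The data describe alternative splicing in mouse embryonic fibroblasts that lack SRSF10, a splicing factor of the SR protein family, beside wild-type fibroblasts. The series title names adipocyte differentiation as the setting of the study, for which embryonic fibroblasts are a common starting cell. Each genotype was represented by 1 library. The authors' deposited table gave 100 splicing events in 96 genes, with the inclusion level of each event in both libraries. Reads over these events totalled 56927 in the wild-type and 52735 in the deficient library. Reads that could be assigned to a single isoform had a median of 42 per event in the wild-type library (range 5 to 1542) and 38 in the deficient library (range 5 to 1618). No listed event lay in Srsf10 itself, and the level of its transcript was not analysed here, so the genotype rests on the labels alone.

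The comparison asked which splicing events differed between wild-type and SRSF10-deficient fibroblasts. Exons were both included and skipped more often in the deficient library. Inclusion rose in App, the amyloid precursor protein gene, from 55% to 83%. It also rose in Lpin1, a phosphatidate phosphatase gene with a role in adipocyte differentiation, from 16% to 62%. Inclusion fell in the tumour suppressor gene Trp53 from 90% to 56% and in Ect2, which encodes an exchange factor needed for cytokinesis, from 91% to 61%. Among genes of splicing regulators, inclusion rose in Hnrnpa2b1 from 5% to 46% and fell in Ptbp1 from 69% to 48%. The exons of Trp53 and Ptbp1 matched no annotated inclusion transcript.

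Cassette exons made up 71 of the 100 events, 38 with higher and 33 with lower inclusion in the deficient library. Alternative 3′ splice sites accounted for 10 events, 8 higher and 2 lower, and alternative 5′ splice sites for 10, 6 higher and 4 lower. The types are the table's own labels, although the isoform text of Upf1 and Eif4a2, both labelled cassette exons, describes alternative 5′ splice sites. Of 7 retained introns, 2 were higher and 5 lower, and the 2 mutually exclusive pairs went 1 each way. In all, 55 events had higher and 45 had lower inclusion. The median difference was 35 points among the higher events and -31 points among the lower ones, and every listed event differed by at least 20 points and at most 66. By Fisher's exact test on isoform-exclusive reads, 86 of the 100 events passed, 49 higher and 37 lower. These were 62 of 71 cassette exons, 9 of 10 alternative 3′ splice sites, 6 of 10 alternative 5′ splice sites, 7 of 7 retained introns and both mutually exclusive pairs.

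**Figure D1:**
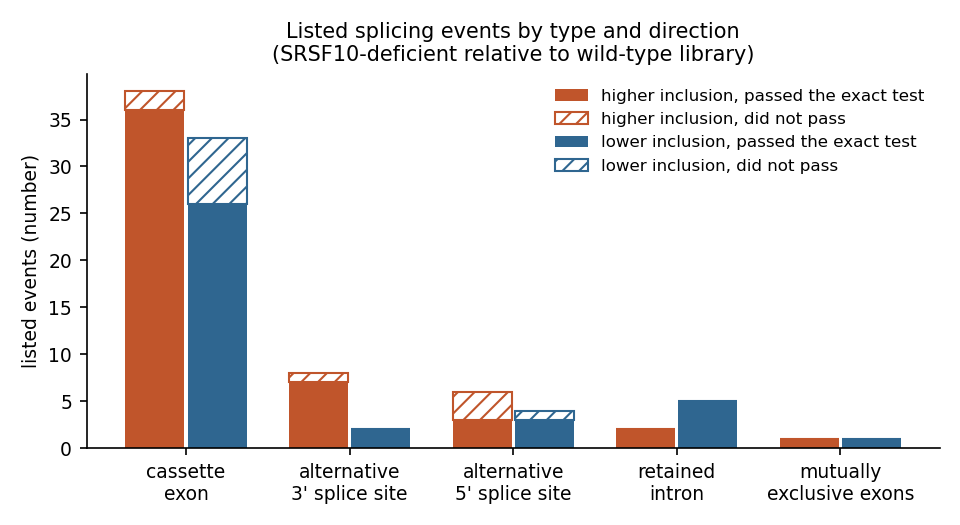
Number of listed events (y axis) by event type (x axis), split by direction in the SRSF10-deficient library; filled bars passed Fisher's exact test on exclusive reads and hatched parts did not. Cassette exons number 38 higher and 33 lower, and retained introns are the type with more lower (5) than higher (2) events.

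Among cassette exons, inclusion rose by 66 points in Cfap300, a gene of motile cilia, and in Usp1, a deubiquitinase gene of DNA repair. The 67-nucleotide coding exon of Cfap300 (mm9 chromosome 9, 8023900 to 8023966) went from 24% (authors' interval 13% to 37%) to 90% (79% to 97%). The exclusive reads behind these values were 11 for inclusion and 29 for exclusion in the wild-type library, and 40 and 3 in the deficient library (Fisher's exact test, adjusted p = 7.56e-09). Usp1 had 2 overlapping versions of its second exon in the table, which rose from 29% to 95% and from 32% to 95%. These versions share an end and much of their reads, and neither had an exclusion read among 32 exclusive reads in the deficient library, which allows an exclusion share of up to 9.38%. In the share of inclusion-only reads the Usp1 rises were 35.5 and 32.4 points. Adnp, a homeobox gene, rose from 32% to 79% at a 5′ UTR exon.

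The 136-nucleotide exon of Hnrnpa2b1 in its 3′ UTR (mm9 chromosome 6, 51411919 to 51412054) rose from 5% (2% to 9%) to 46% (34% to 59%), with 7 of 85 exclusive reads for inclusion in wild-type and 35 of 55 in deficient cells (Fisher's exact test, adjusted p = 3.68e-11). Immt, which encodes a scaffold of mitochondrial cristae, rose from 19% to 56% at a 96-nucleotide coding exon. Zfp219, a zinc finger gene, rose from 21% to 56%, Rint1, a gene of vesicle tethering, from 60% to 94%, and Slc4a1ap from 14% to 45%.

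Falls among cassette exons with at least 20 exclusive reads in each library included Phc1, Msl1, Trp53 and Ect2. Phc1, a Polycomb gene, fell from 78% to 43%, and Msl1, a gene of a histone acetyltransferase complex, from 52% to 17%. Trp53 fell at a 412-nucleotide exon that matched no annotated inclusion transcript (mm9 chromosome 11, 69394556 to 69394967), on 41 of 43 exclusive reads for inclusion against 20 of 30 (Fisher's exact test, adjusted p = 0.00498). Ndrg4 fell from 58% to 25%, and Taf6l, which encodes a subunit of histone acetyltransferase complexes, from 91% to 60%. The Taf6l exon also matched no annotated inclusion transcript. Thrap3, a gene of mRNA processing, fell from 39% to 8%. The 67-nucleotide exon of Ect2 (mm9 chromosome 3, 27014988 to 27015054) fell on 195 of 206 against 68 of 86 exclusive reads (Fisher's exact test, adjusted p = 0.000682), a difference of -15.6 points in these reads. Samhd1, which encodes a nucleotide hydrolase, fell from 45% to 15%, the HMG-box gene Hmgxb4 from 71% to 41%, and a 116-nucleotide exon of Ktn1, the gene of kinectin, from 36% to 6%. Hmgxb4 and this Ktn1 exon no longer passed with inclusion reads divided by 2 (Fisher's exact test, adjusted p = 0.0775 and 0.0836).

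**Figure D2:**
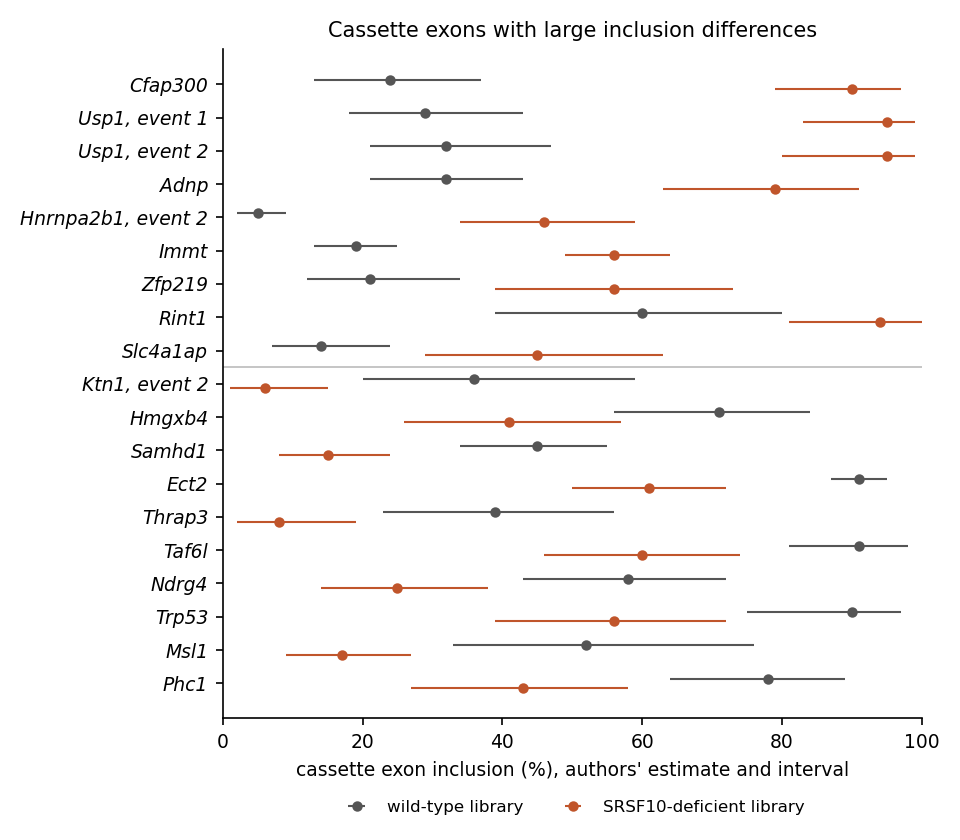
Inclusion in percent (x axis) of 9 cassette exons with large rises (above the grey line) and the 10 with the largest falls (below it) among those that passed with at least 20 exclusive reads in each library, named on the y axis, in the 1 wild-type library (grey) and the 1 SRSF10-deficient library (orange); points are the authors' estimates and lines their intervals. The intervals of Cfap300 (13% to 37% and 79% to 97%) lie apart, while those of Hmgxb4 (56% to 84% and 26% to 57%) overlap.

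Splice site choice changed in Pcna, Xrn1 and Mecom, among others. At alternative 5′ splice sites, use of the longer exon rose in Pcna, the gene of the replication clamp, from 61% to 97% on 182 of 221 against 296 of 298 exclusive reads (Fisher's exact test, adjusted p = 2.76e-12). It also rose in Xrn1, an exoribonuclease gene, from 14% to 51%, and in Arid1a, a chromatin remodeller gene, from 27% to 50%. It fell in Pcmt1, a protein repair enzyme gene, from 85% to 60%, and in 0610010K14Rik from 42% to 20%. At alternative 3′ splice sites, the longer exon rose in Mecom, a zinc finger gene, from 37% to 72%. In Hspbp1, an Hsp70-binding protein gene, 2 near-identical versions rose from 42% to 77% and from 45% to 77%. The kinase gene Dyrk1b fell from 60% to 26%. The share of inclusion-only reads gave smaller differences for Pcna (17.0 points), Mecom (13.2 points, on 214 of 260 against 192 of 201 reads) and Pcmt1 (-14.4 points). This share is not corrected for the length of the alternative part, 972 nucleotides in Mecom, so both measures are on unlike scales.

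Intron retention rose in the ribosomal protein gene Rpl13a from 29% to 78% and in Tomm40, a mitochondrial import gene, from 26% to 54%. It fell in the kinase gene Camk1 from 54% to 10%, in Zcchc2 from 46% to 23% and in the RNA-binding protein gene Hnrnph1 from 35% to 13%. Between mutually exclusive exons, use of the upstream exon fell in Pkm, the gene of muscle pyruvate kinase, from 38% to 17%, and rose in Atp8a1, a phospholipid flippase gene, from 41% to 68%. The authors' intervals overlapped for Rpl13a (13% to 53% and 43% to 97%) and for Atp8a1 (26% to 57% and 50% to 85%). In the share of inclusion-only reads the difference was -13.8 points in Camk1, on 71 of 72 against 56 of 66 reads, and 21.7 points in Rpl13a, on 18 of 23 against 30 of 30 reads, while in Hnrnph1 it was -33.1 points.

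Lpin1 has an established role in adipocytes, and its event was named whatever its value. The exon is a 144-nucleotide 5′ UTR exon (mm9 chromosome 12, 16591314 to 16591457), the second of 21 exons of a transcript that is not the principal one. Inclusion rose from 16% (3% to 37%) to 62% (47% to 78%). The exclusive reads were 1 of 8 for inclusion in the wild-type library, a share of 12.5% (exact 95% interval 0.316% to 52.7%), and 26 of 35 in the deficient library, a share of 74.3% (56.7% to 87.5%). The difference passed Fisher's exact test (adjusted p = 0.00472), but not with inclusion reads divided by 2 (adjusted p = 0.0519, Fisher's exact test). Only 150 reads covered the event in the wild-type library, against 689 in the deficient one.

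Of the gene lists, splicing factors and RNA-binding proteins held the most events, 9 in 8 genes, 5 higher and 4 lower. Of these, 8 passed both over all events and adjusted over the list alone. Adjustment over a list alone is no separate support here or below, because list members come from the same selected events. Hnrnpa2b1 rose at its 3′ UTR exon, while its second event, an alternative 5′ splice site, stood at 24% and 81% on 7 and 36 exclusive reads and did not pass (Fisher's exact test, adjusted p = 0.261). Both Hnrnpa2b1 events share the exon boundary at 51412054 and the same both-isoform reads, 159 in the wild-type and 97 in the deficient library. They overlap and are not separate observations. Rbm5 rose from 58% to 97%, Celf1 from 11% to 41% and Celf2 from 70% to 90%. Thrap3 fell as given above, Hnrnpr fell from 89% to 63%, Ptbp1 from 69% to 48% and Hnrnph1 as a retained intron. The Ptbp1 exon matched no annotated inclusion transcript. In the share of inclusion-only reads Hnrnpr differed by -16.2 points. Rbm5, Celf1, Celf2 and Ptbp1 are named after their values were seen.

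The fixed list of 162 chromatin and transcription regulators, which does not include Phc1, Msl1 or Taf6l, had 7 events, 4 higher and 3 lower, and all 7 passed, also adjusted over the list alone. Crem, a cAMP-responsive transcription factor gene, rose from 16% to 66% and Arid1a at its 5′ splice site. The histone methyltransferase gene Nsd2 fell from 76% to 19% and E2f6, a repressor gene of the E2F family, from 95% to 48%. Crem, Nsd2 and E2f6 each had fewer than 20 exclusive reads in at least 1 library. The reads for inclusion were 2 of 11 against 10 of 13 in Crem and 14 of 15 against 3 of 11 in Nsd2. In E2f6 they were 29 of 29 against 6 of 10. The Crem exon did not pass with inclusion reads divided by 2 (Fisher's exact test, adjusted p = 0.0537). In the fixed list of 144 cell cycle, DNA repair and apoptosis genes, which does not include Usp1 or Pcna, the 3 events fell and passed, also adjusted over the list alone. They lay in Trp53, Ect2 and Cdk11b, a cyclin-dependent kinase gene that went from 62% to 13%. Cdk11b rested on 9 of 12 against 1 of 11 exclusive reads for inclusion, under the minimum of 20 in each library. The Cdk11b exon missed the threshold with inclusion reads divided by 2 (Fisher's exact test, adjusted p = 0.0523).

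Cytoskeletal genes had 6 events in 5 genes, 1 higher and 5 lower, of which 5 passed, also adjusted over the list alone. Ktn1 contributed the rise, a 72-nucleotide coding exon that went from 39% to 85%, and also a fall, at the 116-nucleotide exon. The 72-nucleotide exon rested on 5 exclusive reads in the wild-type library and did not pass with inclusion reads divided by 2 (Fisher's exact test, adjusted p = 0.0692). Tjp1, a tight junction gene, was listed with a fall from 79% to 39%, but every read count of this event was identical to that of the Upf1 event. In the fixed list of 153 membrane trafficking genes, which does not include Rint1 or Rab11fip1, the 2 events rose and passed, also adjusted over the list alone. They were App, at a 57-nucleotide coding exon (mm9 chromosome 16, 85040496 to 85040552) with 1002 of 1542 against 1426 of 1618 exclusive reads (Fisher's exact test, adjusted p = 5.04e-53), and the endocytosis gene Eps15, from 65% to 92%.

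Both events in the signalling list, Camk1 and Dyrk1b, fell and passed, also adjusted over the list alone. This fixed list of 151 genes does not include the phosphatase-related genes Mtmr3 and Ppp1r16a, named after their values were seen. Their cassette exons passed with rises from 25% to 47% and from 20% to 44%. Ppp1r16a did not pass with inclusion reads divided by 2 (Fisher's exact test, adjusted p = 0.0642). Of SRSF10 targets reported in other cell systems, 3 genes appeared, Lpin1 with a rise and Pkm and Lrrfip1 with falls, the last from 68% to 43%. All 3 passed, also adjusted over the list alone. This list was matched by gene, and neither exon nor direction was compared with the reported targets. Lpin1 is known for SRSF10 from work on adipocytes that may include these libraries, so its presence is not independent evidence. The adipocyte and lipid list held 2 events, Lpin1 and Acly, the gene of ATP citrate lyase, and 1 of these passed, also adjusted over the list alone. Acly stood at 84% and 18% in the authors' estimates. Its exclusive reads were 103 of 105 for inclusion in the wild-type and 11 of 11 in the deficient library, which is the opposite order (Fisher's exact test, adjusted p = 1). None of the listed events lay in the 107 genes of the fixed list for extracellular matrix and adhesion or in the 54 markers of other cell types. The table does hold Loxl4, a matrix cross-linking gene outside that list and named after its values were seen, whose longer exon fell from 78% (48% to 95%) to 29% (9% to 52%), with overlapping intervals. It rested on 6 of 7 against 3 of 12 exclusive reads (Fisher's exact test, adjusted p = 0.026), too few for the minimum of 20 in each library.

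Cassette exons lay in coding sequence for 26 of the 63 that matched an annotated transcript, and in the 5′ UTR for 11. Another 13 held a start or stop codon of a matched transcript, 8 were coding in some transcripts and in the 3′ UTR of others, 1 was in a 3′ UTR and 4 were in noncoding transcripts. Of the 11 exons in the 5′ UTR, 8 rose, Lpin1 and Adnp among them, and 3 fell, in Nsd2, Txnrd1 and Fbxo34. Of all 63 matched exons, 37 rose and 26 fell, and the 5′ UTR split was not tested against this one. Of the 26 coding exons, 19 had a length that was a multiple of 3, 11 of 14 with higher and 8 of 12 with lower inclusion. The second exon of the transcript was the cassette exon in 28 of the 63 cases. Txnrd1, Fbxo34 and the exon classes were chosen after their values were seen.

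The 14 events that did not pass included 9 with fewer than 20 exclusive reads in a library, such as Hnrnpa2b1 at its 5′ splice site, and 5 with more, among them Enpp2, Palm, Dcaf1 and Emsy, named after their values were seen. At these depths a difference in them was not detectable from exclusive reads alone. The difference between the libraries in the deposited inclusion lay a median of 7.41 points from that in the share of inclusion-only reads, and 67.9 points from it in Acly.

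**Figure D3:**
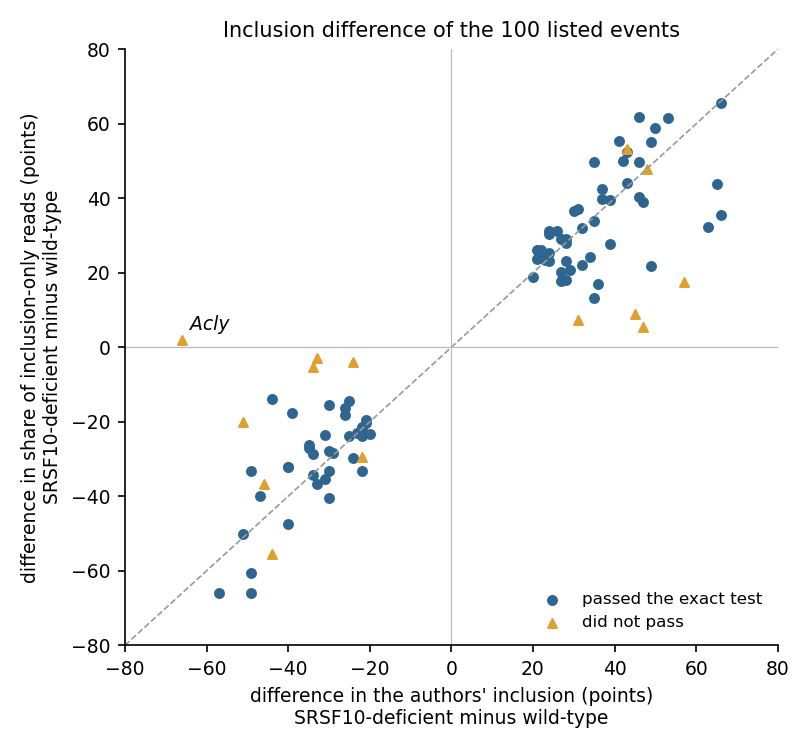
Difference between the 2 libraries (deficient minus wild-type, in points) in the authors' inclusion (x axis) and in the share of inclusion-only among isoform-exclusive reads (y axis) for the 100 listed events, 1 point per event; circles passed Fisher's exact test, triangles did not, and the dashed line marks equal values. Acly is the event whose differences have opposite signs, -66 and 1.90 points.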

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

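All tests in this part were chosen after the result was seen.

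The number of reads over the listed event, a measure that the comparison of inclusion does not use, was set against a limit of 1.5 times the wild-type library after scaling by the median ratio over all genes of the table. In 2 genes the whole exact 95% interval of the ratio lay above that limit. Lpin1 had 4.91 times as many reads in the deficient library (4.11 to 5.90) and Celf2, an RNA-binding protein gene, 1.92 times as many (1.79 to 2.07). These ratios describe the 2 libraries and combine transcript level with the isoform change over the event.

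The events listed for Tjp1 and Upf1 carried identical read counts and estimates. Upf1 is labelled as a cassette exon in the table, but its isoform text describes an alternative 5′ splice site, as for Tjp1. The longest exon is 118 nucleotides in Upf1 and 1510 in Tjp1, and long exons add reads that fit both isoforms. Such reads made up 93.6% of the 870 isoform-compatible reads, with a lower 95% bound of 91.7%. That bound lies above the 51.0% that was the highest share among 5 other events of this type with every exon under 300 nucleotides. Among 5 events with longer exons the share ranged from 22.6% to 98.4%, but its upper end came from Eif4a2, labelled a cassette exon in the table. Without Eif4a2 the other 4 reached 85.6%, also below the lower bound of the pair. By the same rule the pair then lies outside both groups, so the share cannot tell which gene the values belong to. No biological explanation was tested for this pattern.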

How the results depend on the processing

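The event type by the isoform text, the share of inclusion-only reads, the Bayes factor and the removal of 4 doubtful events were chosen after seeing the data. No paired analysis was possible because each genotype has 1 library. The count of 86 events became 62 at an adjusted p under 0.01, 75 with inclusion reads divided by 2, 63 of 68 with at least 20 exclusive reads in each library, and 82 of 96 without the Tjp1 and Upf1 events and the second Usp1 and Hspbp1 events. All 62, 75, 63 and 82 were among the 86. A minimum difference of 20 points, or none, changed nothing, since every listed event reaches 20. A Bayes factor of at least 10 kept 96 events, including all 14 that did not pass Fisher's exact test.

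At an adjusted p under 0.01, passing alternative 3′ splice sites fell from 9 to 5, alternative 5′ splice sites from 6 to 3, retained introns from 7 to 4 and mutually exclusive pairs from 2 to 1. By Bayes factor, 10 alternative 5′ splice sites and 1 mutually exclusive pair remained. With at least 20 exclusive reads in each library, the listed alternative 5′ splice sites were 3 higher and 2 lower, the lower alternative 3′ splice sites 1 and the lower retained introns 3, whose median difference went from -40 to -23 points. Over all 5 lower retained introns, dividing inclusion reads by 2 gave a median of -27.7 points. Higher alternative 5′ splice sites had a median of 42 points in the table and 21.0 points from exclusive reads, the same with division since it leaves splice sites untouched, and higher retained introns 38.5 and 24.8 points. Counting each gene once left 0 higher events in the cytoskeletal list, because Ktn1 then counts by its falling exon. For the other changes the cause was not tested, except that stricter thresholds and read minimums leave fewer events by construction.

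Of the 49 named events, Acly turned direction, at 1.90 points from exclusive reads and 3.74 points with inclusion reads divided by 2. The other named events kept their direction under every alternative run. Of the 47 that passed, 12 no longer did at an adjusted p under 0.01 and 6 no longer did with inclusion reads divided by 2. Depth limits these results, as 32 events have fewer than 20 exclusive reads in a library.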

Other observations

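The tests of chromosome position and of Apobec3 were chosen after the result was seen, while those of purine-rich sequence were set out before.

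Reads over the event were fewer in the deficient library for 7 genes whose scaled ratio had an upper 95% bound under 1/1.5. Txnrd1, the gene of cytosolic thioredoxin reductase, had a ratio of 0.263 (0.220 to 0.313) and Usp1 one of 0.404. Atp2c1 stood at 0.431 and Tomm40 at 0.480. The RNA-binding protein genes Celf1 and Raly stood at 0.480 and 0.522, and the lipid synthesis gene Acly at 0.519. All 7 genes are listed for an inclusion difference by construction, because reads were counted only over listed events. The events of Acly and Atp2c1 did not pass Fisher's exact test on exclusive reads. In Txnrd1 inclusion fell from 98% to 59%, on 474 of 477 exclusive reads for inclusion against 9 of 11. The deficient library there is under the minimum of 20 reads. The Txnrd1 difference in the share of inclusion-only reads was -17.6 points. In Raly inclusion rose from 51% to 74%.

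Apobec3, a cytidine deaminase gene that restricts retroviruses, had 0 of 16 exclusive reads for inclusion of a 99-nucleotide exon in the wild-type library, which allows a share of up to 18.8%, and 11 of 21 in the deficient one. Inclusion of an internal exon of this gene is known to vary between mouse strains. An inherited allele is a candidate explanation beside the loss of SRSF10, and the 2 cannot be told apart from the 11 inclusion reads, because read sequences were not analysed here and each genotype has 1 library. If variants near Srsf10 on chromosome 4 had been carried along with its loss, listed genes could crowd on that chromosome. There were 8 of 95 listed protein-coding genes on it, against a median of 6 in 10000 random draws of genes, whose central 95% reached up to 11, so the count does not decide between linked variants and none. Hnrnpr lies 0.455 Mb and Arid1a 2.18 Mb from Srsf10 in GRCm38.

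A hypothesis for the opposite directions was that SRSF10, which binds purine-rich RNA, might act by where its sites lie, favouring inclusion from the cassette exon and skipping from the exon downstream. Hexamers of A and G, with both bases present, covered 4.82% of positions in 26 cassette exons listed as lower in the deficient library and 3.60% in 36 listed as higher, 8 of which in all did not pass the test on reads. This difference exceeded 84.4% of 10000 random reassignments of direction, and stayed inside the central 95% set beforehand as the limit. In the downstream exon the densities were 5.49% and 3.81%, the order opposite to the one predicted. The predicted difference, higher minus lower, exceeded 5.85% of reassignments, also inside that limit. With only the exons that passed, chosen after seeing the data, the densities were 4.70% in 20 lower and 3.24% in 34 higher cassette exons (89.6% of reassignments) and 5.89% and 3.83% downstream (4.85%), inside the same limit. The data therefore neither exclude nor favour either part of this hypothesis.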
